A study of Homo sapiens with 12 samples.

How the data were processed

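RNA from HEK293 cells treated with siRNA pools against RBM17, U2SURP or CHERP, or with a non-targeting control siRNA whose label names no pool, was sequenced from 12 libraries, 3 per group, prepared per the labels' protocols with a stranded poly(A) mRNA kit. The authors deposited raw counts of reads per Ensembl gene for each library. Per the submitters' processing notes, HISAT2 2.0.5, SAMtools and HTSeq and the build GRCh38 were used, with no roles given; the annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and its antisense partner may therefore be mixed, and of the 52 genes named for the size of their change 24 overlap another tested gene. Genes with near-identical copies, such as ribosomal protein, histone, calmodulin and mitochondrial genes with nuclear copies, are uncertain where reads could be split. The files hold genes alone, without rows for unassigned reads, so the planned share of reads outside annotated exons was not computed.

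Groups came from the labels. Replicate numbers follow accession order and pair nothing; deviations of equally numbered libraries from their group means correlated between -0.0502 and 0.0648. Library numbers run in blocks by group, so a preparation batch cannot be told apart from the group. Those of U2SURP and CHERP knockdown adjoin (8175 to 8180), while RBM17 knockdown (8162 to 8164) and control (8169 to 8171) stand apart. Replicates differed beyond sampling noise in each pair (chi-square per gene 11.7 to 51.7), so none was treated as a duplicate. Of 60554 gene IDs, 57041 were named by GENCODE 29 (GRCh38), and the 3513 others kept their ID.

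Counts were filtered with filterByExpr, which left 29003 genes, scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3), robust quasi-likelihood, with all 4 groups in a single fit that shares the estimate of spread. The common biological coefficient of variation was 0.0866. Each knockdown was compared with control and with each other knockdown, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SE is the absolute log2 fold change divided by the square root of F. Totals of 252505520 to 320986785 counts per library keep counting error small except for genes of low counts, so for most genes the spread between libraries sets the precision (median SE 0.136 log2 units in RBM17 knockdown).

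Gene lists, 29 in number, were fixed before the data were examined, with lists of markers of other cell types among them, and 87 tests (29 lists in 3 knockdowns) were adjusted together. They were tested with fry (limma 3.58.1), which asks whether the genes of a list move on balance one way and does not compare them with other genes. Camera with its preset and with an estimated correlation was run beside it, and no list was called against control with an estimated correlation. Direct contrasts of the lists between knockdowns were adjusted together as a family of 87 and tested in both ways. Named genes were also set by rule beforehand: RBM17, U2SURP and CHERP; per knockdown the 7 largest increases and decreases among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between libraries of the groups; 4 per direction in direct contrasts; 6 per direction among genes called alike in all 3 knockdowns; and per described list up to 2 called members in each direction by smallest p. Some genes that meet the rule are not reported here and were not replaced. Between groups of 3, chance gives no overlap for 10% of genes.

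On simulated counts for RBM17 knockdown against control, with 200 genes changed among 28032, 77.6% of genes changed by 0.5 log2 units, 98.5% at 1 and 100% at 2 were recovered, and 12 unchanged genes were called. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not tested. Nor does this simulation test scaling or false calls where a large share of genes changes. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, fits of the 2 compared groups, a 2-fold minimum, protein-coding genes alone and leaving out each library. Offsets for GC content and length, and a fit without RBM17 knockdown library 2 and control library 3 (those with the fewest genes in their groups), were added after seeing the data. The offsets were fitted on genes of higher expression and extended to the rest. Figures were drawn with matplotlib 3.10.9.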

Results

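HEK293 is a human cell line of embryonic kidney origin; the labels give HEK293 as the source and HEK293T, a derivative that carries the SV40 large T antigen, as the cell line. The cells received a pool of siRNAs against RBM17, U2SURP or CHERP, or a control siRNA, with 3 libraries per group and 12 in all. The series record calls the control a scramble sequence, and its label reads ON-TARGET plus Non-targeting siRNA #3. The labels of the knockdowns name a SMARTpool and that of the control does not, so the groups may differ in this too. RBM17, U2SURP and CHERP are RNA-binding proteins linked to the U2 small nuclear ribonucleoprotein, which recognises the branch site of introns. The design asks how the transcriptome changes when each of the 3 is depleted, and how far the changes overlap. Total gene counts ran from 252505520 to 320986785 per library. Throughout, expression is in CPM, read counts scaled to the size of the library, as mean ± SD over the 3 libraries of a group, and log2 fold changes are given ± SE from edgeR's quasi-likelihood fit with Benjamini-Hochberg adjusted p-values. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

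Each siRNA pool lowered its own target in all 3 libraries. RBM17 (ENSG00000134453; GRCh38 chromosome 10, 6088987 to 6117457, plus strand) fell from 115 ± 2.73 CPM in control to 26.5 ± 0.523 CPM, which is 23% of control (log2 -2.12 ± 0.049, adjusted p = 1.37e-19). U2SURP (ENSG00000163714; chromosome 3, 142964497 to 143060546, plus strand) fell from 471 ± 33.3 to 144 ± 5.65 CPM, 30.5% of control (log2 -1.71 ± 0.062, adjusted p = 7.05e-15). CHERP (ENSG00000085872; chromosome 19, 16517889 to 16542530, minus strand) fell from 61.3 ± 1.06 to 18 ± 0.788 CPM, 29.3% of control (log2 -1.77 ± 0.053, adjusted p = 4.45e-17). Effects on the other complex members were smaller. CHERP rose in RBM17 knockdown (0.26 ± 0.051, adjusted p = 1.10e-04) and U2SURP rose in CHERP knockdown (0.26 ± 0.060, adjusted p = 9.92e-04); without CHERP knockdown library 3 the latter was 0.17 (adjusted p = 0.0304, the highest over its alternatives). U2SURP in RBM17 knockdown (0.12 ± 0.060, adjusted p = 0.0952), RBM17 in U2SURP knockdown (0.083 ± 0.047, adjusted p = 0.16), RBM17 in CHERP knockdown (0.093 ± 0.047, adjusted p = 0.107) and CHERP in U2SURP knockdown (-0.027 ± 0.051, adjusted p = 0.71) did not pass the threshold. U2SURP in RBM17 knockdown passed it without control library 3 (0.16, adjusted p = 0.0301) and under other alternatives, the adjusted p running from 0.018 to 0.427. The DESeq2 Wald test also called RBM17 in U2SURP knockdown (0.112, adjusted p = 0.0451, range over its alternatives 0.0451 to 0.373) and in CHERP knockdown (0.117, adjusted p = 0.0325, range 0.0325 to 0.638), and offsets for GC content and length called CHERP in U2SURP knockdown (0.108, adjusted p = 0.0435, range 0.0435 to 0.989).

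**Figure D1:**
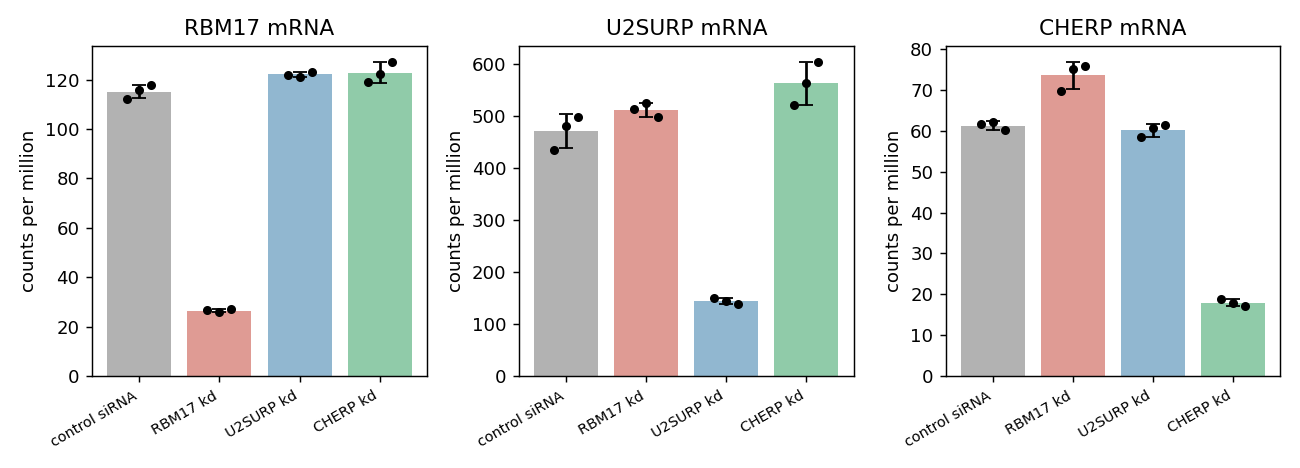
Expression of RBM17, U2SURP and CHERP in CPM (vertical axes, from 0) in the 4 groups, with bars for means, error bars for the SD and points for the 3 libraries. Each mRNA is lowest under its own siRNA pool, at 26.5, 144 and 18 CPM.

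The 12 libraries separated by group. The first principal component of log2 CPM, with 31.0% of the variance, set the RBM17 knockdown libraries apart, and the second, with 21.3%, set the controls apart from the knockdowns. Control library 3 lay nearer to the RBM17 knockdown on the first component (8.26) than controls 1 and 2 (25.1 and 28.2). Mitochondrially encoded genes took 8.29 ± 0.41% of counts in control libraries against 4.86 ± 0.195% in RBM17, 5.06 ± 0.104% in U2SURP and 4.25 ± 0.325% in CHERP knockdown.

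**Figure D2:**
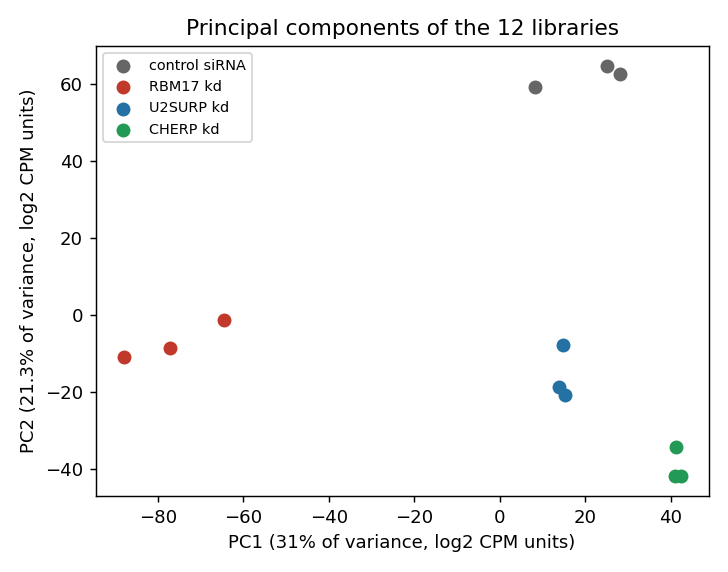
First and second principal components of log2 CPM (horizontal and vertical axes, log2 CPM units), one point per library, coloured by group. RBM17 knockdown libraries lie between -88.0 and -64.5 on the first component and all other libraries at or above 8.26.

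RBM17 knockdown raised most members of the neuronal gene list and lowered EGR1, ARC, FOS and the ribosomal protein mRNA RPS6. RAB3C, a synaptic vesicle GTPase, rose 3.95-fold, from 2.44 ± 0.164 to 9.65 ± 0.259 CPM (adjusted p = 6.58e-14). RPS6, a protein of the small ribosomal subunit, fell 9.61-fold, from 1353 ± 124 to 141 ± 6.14 CPM (adjusted p = 3.43e-20). Heat shock and spliceosome genes were mostly higher, and all 13 mitochondrially encoded mRNAs were lower.

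Other large increases were in AP3B2, a neuronal adaptor subunit (1.97 ± 0.097), SYT14 (1.72 ± 0.10), CACNA1B, an N-type calcium channel (1.67 ± 0.071), TMEM145 (1.56 ± 0.072) and C8orf33 (1.52 ± 0.068). After RPS6, the largest decreases were in EGR1 (-2.54 ± 0.28), ARC (-2.38 ± 0.21) and FOS (-2.32 ± 0.33), which are immediate-early genes, and in ALDH8A1 (-2.37 ± 0.11), RBM17 itself and PAQR6 (-2.11 ± 0.090). Of the neuronal list, 20 of 35 members rose and 8 fell (20 and 8 adjusted over the list alone), with a median of 0.63 (fry adjusted p = 1.28e-06). CHGA, a granin of secretory granules, rose by 3.45 ± 0.18 and SYP, a synaptic vesicle protein, by 1.31 ± 0.071, while KIF5A (-0.54 ± 0.063) and STMN4 (-1.62 ± 0.33) fell. The neuronal call was lost with an estimated correlation (adjusted p = 0.109).

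Several lists of splicing factors, though not all, were higher on balance. Among U2 snRNP genes, 16 of 20 members rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.40 (fry adjusted p = 2.58e-04), with SNRPA1 at 0.69 and SF3A3 at 0.66, against DDX46 at -0.51. Sm proteins form the core ring of the spliceosomal particles, and 7 of 7 members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.57 (fry adjusted p = 2.62e-04); SNRPB rose by 0.78 ± 0.059. For the other spliceosome components, 37 of 48 members rose and 7 fell (38 and 8 adjusted over the list alone), with a median of 0.40 (fry adjusted p = 1.75e-04); SNRPC (1.11) and PPIL1 (0.94) rose and LUC7L3 (-1.03) and LUC7L (-0.87) fell. Of the hnRNP genes, 21 of 26 members rose and 4 fell (21 and 4 adjusted over the list alone), with a median of 0.46 (fry adjusted p = 1.91e-04), with HNRNPM at 0.95. In the list of nonsense-mediated decay and exon junction factors, 14 of 21 members rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.30 (fry adjusted p = 2.14e-04), with EIF4A3 at 0.75 and MAGOH at 0.93. The splicing kinases of the CLK and SRPK families and their relatives went both ways: 3 of 12 members rose and 6 fell (3 and 6 adjusted over the list alone), with a median of -0.17 (fry adjusted p = 1.91e-04), with CLK1 at -0.89 and SRPK1 at 0.52. With an estimated correlation the adjusted p was 0.494 for each of these 6 lists. SR proteins did not pass the test: 6 of 17 members rose and 7 fell (6 and 8 adjusted over the list alone), with a median of -0.068 (fry adjusted p = 0.0986), and adjusted p = 0.822 with an estimated correlation. Without control library 1 that list passed, pointing down (adjusted p = 0.0372, range over its alternatives 2.80e-04 to 0.87), as it did with offsets for GC content and length. The RBM proteins and other splicing regulators did not pass the main test either: 18 of 39 members rose and 15 fell (18 and 15 adjusted over the list alone), with a median of -0.027 (fry adjusted p = 0.186), the test pointing up, and adjusted p = 0.837 with an estimated correlation. This list passed under DESeq2 size factors, with fits of 2 groups and without RBM17 knockdown library 1 (adjusted p = 0.00984, 0.0262 and 0.0258, range over its alternatives 0.00984 to 0.913).

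Among stress and growth programmes, heat shock genes rose: 15 of 17 members rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.65 (fry adjusted p = 4.65e-05). HSPH1 (1.17 ± 0.065) and STIP1 (1.05 ± 0.058), both co-chaperones, were among the higher members of the list, whose adjusted p was 0.361 with an estimated correlation. Of mitosis genes, 35 of 43 members rose and 2 fell (37 and 3 adjusted over the list alone), with a median of 0.45 (fry adjusted p = 9.30e-05), CDC20 rising by 0.89 and the proliferation marker MKI67 at -0.64. For hypoxia and glycolysis, 22 of 31 members rose and 5 fell (22 and 5 adjusted over the list alone), with a median of 0.40 (fry adjusted p = 5.06e-04), with TPI1 at 0.95 and PGAM1 at 0.85, both glycolytic enzymes. Of the 13 mitochondrially encoded mRNAs, 0 of 13 members rose and 13 fell (0 and 13 adjusted over the list alone), with a median of -0.71 (fry adjusted p = 1.16e-04), MT-CYB falling from 4939 ± 474 to 2386 ± 110 CPM. These last 3 lists each had an adjusted p of 0.494 with an estimated correlation. DNA replication genes rose as well: 23 of 35 members rose and 4 fell (23 and 5 adjusted over the list alone), with a median of 0.43 (fry adjusted p = 0.00102). The camera adjusted p of that list was 0.494 with an estimated correlation. No direct contrast of it passed fry (adjusted p = 0.765 for RBM17 and U2SURP, 0.582 for RBM17 and CHERP, 0.765 for U2SURP and CHERP knockdown). Markers of other cell types were lower beside these groups: medians were -0.41 for fibroblast genes (fry adjusted p = 4.83e-05), -0.26 for blood genes (fry adjusted p = 0.00253) and -0.58 for epithelial genes (fry adjusted p = 5.37e-04). With an estimated correlation their adjusted p-values were 0.494, 0.551 and 0.494. Of the tested members, 1 of 14 fibroblast, 2 of 10 blood and 0 of 10 epithelial genes rose, and 8, 4 and 6 fell. Such markers can be near the floor (THY1 at 0.0291 CPM in control). Whether low expression accounts for the shift of these lists was not tested.

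In all, 15858 of 29003 genes differed between RBM17 knockdown and control, 7368 higher and 8490 lower. The balance turned under DESeq2 size factors (8112 higher and 7566 lower). At a change of at least 2-fold there were 3404, of which 2759 were lower. Of 6867 long non-coding genes, 2494 were called lower and 484 higher, whereas 6308 protein-coding genes were higher and 4433 lower. In a fit of protein-coding genes alone, 5665 were higher and 5354 lower.

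In U2SURP knockdown the lists of genes linked to ATF4 and of ribosomal protein genes were higher on balance, and those of endoplasmic reticulum chaperones and sterol synthesis genes lower, none of the 4 passing with an estimated correlation (adjusted p = 0.494 for each). G0S2, an inhibitor of triglyceride lipolysis, rose 4.39-fold, from 8.97 ± 0.938 to 39.4 ± 2.24 CPM (adjusted p = 5.59e-08). NUPR1, a stress-induced nuclear protein, rose 3.89-fold (log2 1.96 ± 0.11, adjusted p = 3.56e-10). ALDH8A1, an aldehyde dehydrogenase, fell 3.96-fold to 3.29 ± 0.326 CPM (adjusted p = 3.01e-12).

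DHRS2 (2.00 ± 0.17), PKD1L1 (1.81 ± 0.093), TXNIP, a thioredoxin-binding protein (1.69 ± 0.067), AKNA (1.68 ± 0.19) and ARRDC3 (1.53 ± 0.27) completed the largest increases. Besides ALDH8A1 and U2SURP, the largest decreases were in TMEM45A (-1.50 ± 0.083), ZCCHC12 (-1.48 ± 0.10), CLSTN2 (-1.40 ± 0.078), the ceramide kinase CERK (-1.38 ± 0.057) and RSRP1 (-1.37 ± 0.10). Of the genes linked to the transcription factor ATF4, 18 of 26 members rose and 4 fell (20 and 4 adjusted over the list alone), with a median of 0.38 (fry adjusted p = 2.62e-04). ATF5 rose by 1.30 ± 0.084, while ATF4 itself fell (-0.62 ± 0.061). The ATF4 list also rose in RBM17 knockdown (18 rose and 4 fell, median 0.335, fry adjusted p = 5.37e-04). In CHERP knockdown 13 rose and 4 fell (median 0.156, fry adjusted p = 0.00138). Both had a camera adjusted p of 0.494 with an estimated correlation. No direct contrast of the list passed fry (adjusted p = 0.413 for RBM17 and U2SURP, 0.436 for RBM17 and CHERP, 0.114 for U2SURP and CHERP). In U2SURP knockdown ribosomal protein genes moved together: 69 of 78 members rose and 0 fell (70 and 0 adjusted over the list alone), with a median of 0.34 (fry adjusted p = 0.00172), with RPS12 at 0.60 and RPS14 at 0.53. Many of these genes have near-identical pseudogenes, so single values are uncertain. For DNA replication, 26 of 35 members rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 0.29 (fry adjusted p = 7.68e-04), with E2F2 at 0.79 and MCM2 at 0.57. With an estimated correlation the adjusted p was 0.494 for each of these 3 lists.

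Lower groups in U2SURP knockdown included the list of endoplasmic reticulum chaperones, which also holds other genes of the unfolded protein response, such as SYVN1. Of this list, 0 of 20 members rose and 17 fell (0 and 17 adjusted over the list alone), with a median of -0.30 (fry adjusted p = 4.16e-04). HSP90B1 fell by 0.68 and SYVN1 by 0.63 on the log2 scale. Of the cholesterol synthesis genes, 4 of 24 members rose and 15 fell (5 and 16 adjusted over the list alone), with a median of -0.29 (fry adjusted p = 2.50e-04), with SQLE at -0.86, while PMVK rose (0.58). SR proteins are splicing regulators with arginine-serine repeats, and 1 of 17 members rose and 9 fell (1 and 9 adjusted over the list alone), with a median of -0.13 (fry adjusted p = 0.00102), with SRSF5 at -0.79 and SRSF2 at -0.43. These 3 lists each had an adjusted p of 0.494 with an estimated correlation. Mitochondrially encoded mRNAs were lower: 0 of 13 members rose and 13 fell (0 and 13 adjusted over the list alone), with a median of -0.68 (fry adjusted p = 1.73e-04), MT-ND1 at -0.84; the adjusted p was 0.343 with an estimated correlation. In the direct contrast, RBM17 minus U2SURP knockdown, spliceosome components had a median of 0.19 (fry adjusted p = 0.00334, and adjusted p = 0.749 with an estimated correlation) and hnRNP genes 0.28 (fry adjusted p = 0.00384, and adjusted p = 0.749 with an estimated correlation). Both lists also rose against control in U2SURP knockdown. Of spliceosome components, 32 of 48 members rose and 8 fell (33 and 9 adjusted over the list alone), with a median of 0.20 (fry adjusted p = 0.00741), and adjusted p = 0.542 with an estimated correlation. Of hnRNP genes, 16 of 26 members rose and 4 fell (16 and 4 adjusted over the list alone), with a median of 0.19 (fry adjusted p = 0.0108), and adjusted p = 0.551 with an estimated correlation. Within U2SURP knockdown, LUC7L (-1.05) and LUC7L3 (-0.91) fell and PPIL1 (0.67) and XAB2 (0.58) rose. Markers of other cell types had medians of -0.35 (fry adjusted p = 6.31e-04, and adjusted p = 0.494 with an estimated correlation) for fibroblast genes, -0.41 (fry adjusted p = 0.00102, and adjusted p = 0.494 with an estimated correlation) for epithelial genes and -0.10 (fry adjusted p = 0.812, and adjusted p = 0.901 with an estimated correlation) for blood genes, whose test pointed up.

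The count of changed genes was 12549 of 29003, 6119 higher and 6430 lower than control. The balance turned under DESeq2 size factors (6625 higher and 5898 lower) and without control library 3 (6220 higher and 6107 lower). With a change of at least 2-fold it was 1578.

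In CHERP knockdown the lists of endoplasmic reticulum chaperones, neuronal genes and targets of CIC and ERK signalling were lower on balance, and those of ribosomal protein genes and p53 targets higher. None of the 5 passed with an estimated correlation (adjusted p = 0.343, 0.158, 0.494, 0.494 and 0.494). ALDH8A1 fell 9.95-fold, from 13.1 ± 1.57 to 1.31 ± 0.0558 CPM (adjusted p = 4.76e-16). SMC1B, a meiotic cohesin subunit, rose 4.18-fold to 13.6 ± 2.13 CPM (adjusted p = 5.62e-13). HSP90B1, an endoplasmic reticulum chaperone, fell 2.53-fold, from 1264 ± 102 to 499 ± 34.6 CPM (adjusted p = 1.68e-13).

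Other genes with the largest increases were NUPR1 (1.93 ± 0.11), PKD1L1 (1.84 ± 0.093), the amino acid transporter SLC43A2 (1.81 ± 0.27), INPP5D (1.77 ± 0.29), TFAP2E (1.71 ± 0.10) and LGR6 (1.69 ± 0.13). The largest decreases after ALDH8A1 were in C11orf96 (-2.55 ± 0.23), GPR50 (-2.28 ± 0.069), CLSTN2 (-2.18 ± 0.080), ARC (-2.09 ± 0.20), the matrix protein TNC (-2.04 ± 0.080) and SCUBE1 (-1.98 ± 0.10). In the list of endoplasmic reticulum chaperones, 0 of 20 members rose and 18 fell (0 and 18 adjusted over the list alone), with a median of -0.53 (fry adjusted p = 3.06e-05). HYOU1 fell by 1.09 on the log2 scale. The adjusted p of the list was 0.343 with an estimated correlation. Among neuronal genes, 3 of 35 members rose and 19 fell (3 and 19 adjusted over the list alone), with a median of -0.50 (fry adjusted p = 3.85e-06), with SYP at -1.40 and L1CAM at -1.65, and ELAVL2 higher (0.61); the adjusted p was 0.158 with an estimated correlation. For CIC and ERK targets, 4 of 25 members rose and 14 fell (4 and 14 adjusted over the list alone), with a median of -0.68 (fry adjusted p = 1.73e-04), with the feedback regulators DUSP4 (-1.40) and SPRED2 (-1.03) among the lower genes. Calcium handling genes were lower on balance: 10 of 34 members rose and 20 fell (10 and 20 adjusted over the list alone), with a median of -0.27 (fry adjusted p = 8.80e-04); the store calcium sensor STIM1 fell by 0.90 on the log2 scale and ATP2A1 rose by 0.94. With an estimated correlation these last 2 lists had adjusted p-values of 0.494 and 0.511. Cholesterol synthesis genes were lower here as in U2SURP knockdown: 3 of 24 members rose and 13 fell, with a median of -0.20 (fry adjusted p = 4.16e-04). The camera adjusted p was 0.494 with an estimated correlation. The direct contrast of U2SURP and CHERP knockdown did not pass fry for this list (adjusted p = 0.457). In RBM17 knockdown 5 rose and 12 fell (median -0.18, fry adjusted p = 0.073, range over its alternatives 0.00207 to 0.804).

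Upward groups in CHERP knockdown began with ribosomal protein genes: 74 of 78 members rose and 1 fell (74 and 1 adjusted over the list alone), with a median of 0.40 (fry adjusted p = 7.68e-04), with RPS12 at 0.68 and RPL17, the member called lower, at -0.29. Of p53 targets, 17 of 24 members rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.41 (fry adjusted p = 0.00406). SPATA18 (0.62) and ZMAT3 (0.65) were among the higher members, and the death receptor TNFRSF10B was lower (-0.41). HEK293T cells carry large T antigen, which binds p53. For DNA replication, 27 of 35 members rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.26 (fry adjusted p = 5.89e-04), with CDT1 at 0.78 and PRIM1 at 0.92. These 3 lists each had an adjusted p of 0.494 with an estimated correlation. Spliceosome components and hnRNP genes rose in CHERP knockdown too. Of the former, 32 of 48 members rose and 8 fell (34 and 8 adjusted over the list alone), with a median of 0.21 (fry adjusted p = 0.019), and adjusted p = 0.625 with an estimated correlation; this call was lost without CHERP knockdown library 3 (adjusted p = 0.12), control library 1 (adjusted p = 0.0758) or control library 2 (adjusted p = 0.0719), the range over its alternatives being 0.00102 to 0.625. Of hnRNP genes, 18 of 26 members rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.22 (fry adjusted p = 0.00394), and adjusted p = 0.54 with an estimated correlation. Mitochondrially encoded mRNAs were lower, and 0 of 13 members rose and 13 fell (0 and 13 adjusted over the list alone), with a median of -0.94 (fry adjusted p = 2.76e-05), MT-CYB at -1.20; the adjusted p was 0.191 with an estimated correlation. Fibroblast markers had a median of -0.42 (fry adjusted p = 3.54e-04, and adjusted p = 0.494 with an estimated correlation), COL6A1 falling by 1.01 on the log2 scale while ACTA2 rose by 1.06. Medians were 0.098 (fry adjusted p = 0.0567, and adjusted p = 0.673 with an estimated correlation) for blood, a list that passed under DESeq2 size factors (adjusted p = 0.041, range over its alternatives 0.00561 to 0.673) and with offsets for GC content and length (adjusted p = 0.00561), and -0.078 (fry adjusted p = 0.0147, and adjusted p = 0.697 with an estimated correlation) for epithelial genes; the epithelial list missed the threshold of fry with offsets for GC content and length (adjusted p = 0.0629, range over its alternatives 0.0126 to 0.697).

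A total of 13731 genes differed from control, 6610 higher and 7121 lower, of 29003 tested; under DESeq2 size factors the balance turned (7040 higher and 6661 lower). At least 2-fold changes were seen in 2347.

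**Figure D3:**
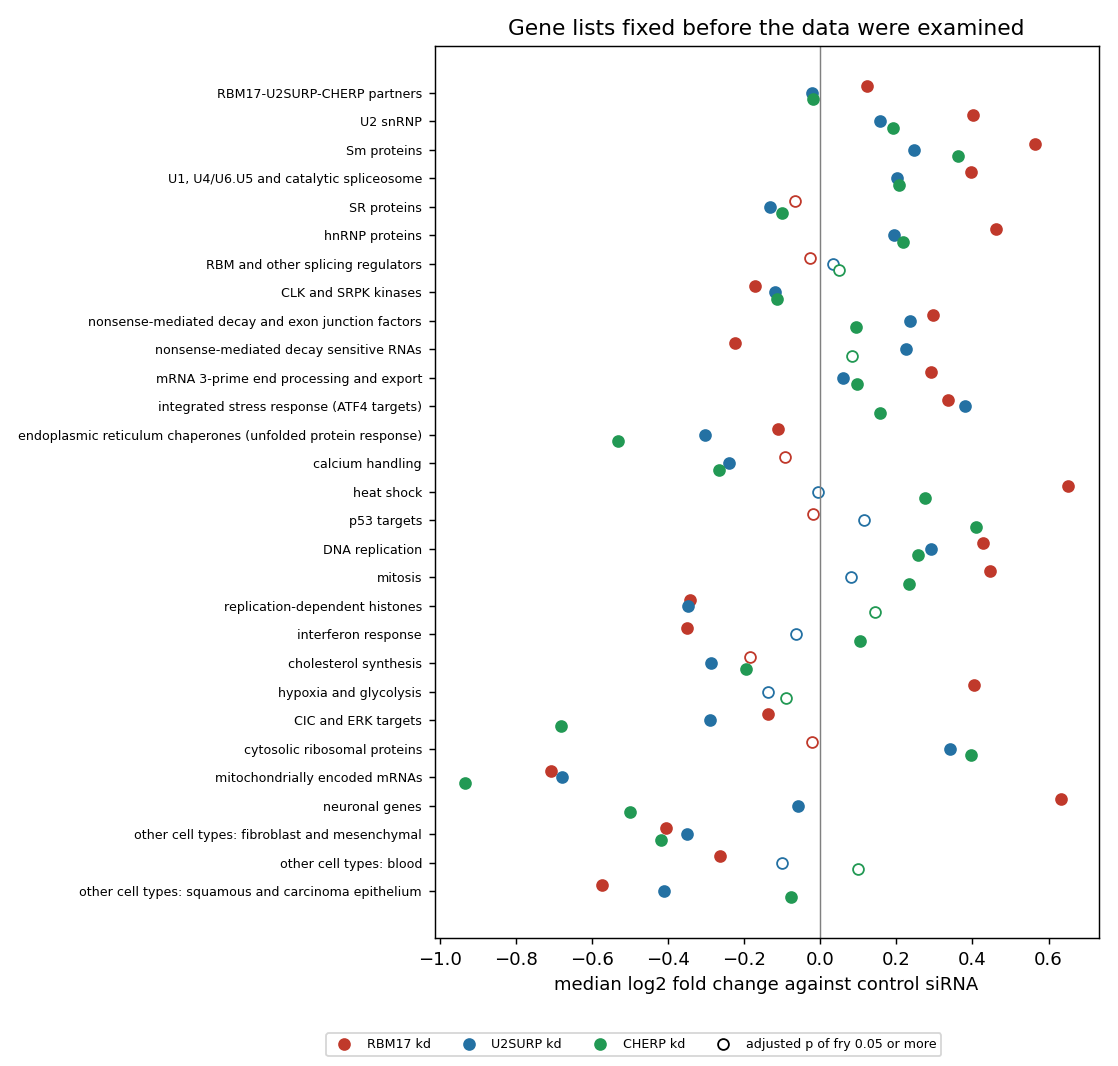
Median log2 fold change against control siRNA (horizontal axis) of each gene list fixed before the data were examined (vertical axis), one point per knockdown. Filled points passed fry at an adjusted p of 0.05; mitochondrially encoded mRNAs lie at -0.71, -0.68 and -0.94 and neuronal genes at 0.63 in RBM17 and -0.50 in CHERP knockdown.

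The 3 knockdowns shared many changes. TXNIP rose in each (log2 1.25, 1.69 and 1.30 in RBM17, U2SURP and CHERP knockdown), as did the co-chaperone DNAJA4 (1.18, 1.54 and 1.58) and ARRDC3 (1.17, 1.53 and 1.47). G0S2, DHRS2 and TIGD6 were the other shared increases of this rank, with TIGD6 at 0.86, 0.89 and 1.15. Ranked by the smallest of the 3 changes, ALDH8A1 fell most (-2.37, -1.99 and -3.32), followed by RSRP1 (-1.63, -1.37 and -1.36). FAM229A, ARC, L3HYPDH and ZCCHC12 also fell in all 3, L3HYPDH by nearly equal amounts (-1.06, -1.04 and -1.07). Altogether 2964 genes were higher in all 3 knockdowns and 3131 lower, where independent lists would share 354 and 462. The balance turned under DESeq2 size factors (3385 higher and 2702 lower) and without control library 3 (3304 higher and 3013 lower).

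Across genes, fold changes correlated at Pearson 0.67 for U2SURP with CHERP, 0.513 for RBM17 with U2SURP and 0.392 for RBM17 with CHERP (jackknife SE over libraries 0.0124, 0.0222 and 0.022); genes are not independent replicates. The same control libraries enter each comparison, and in 50 simulated data sets with unchanged knockdown groups the mean correlation was 0.506, 0.503 and 0.502. So the RBM17 with U2SURP value lay below the highest simulated one (0.531), and the RBM17 with CHERP value below the simulated mean. The simulated correlation comes from the shared controls alone, so these ranks do not show whether real changes were shared. Covariances were 0.26, 0.223 and 0.192, against simulated 0.0525, 0.0525 and 0.0522, which leaves 0.208, 0.171 and 0.14. In the same direction, U2SURP and CHERP knockdown shared 4270 higher and 4570 lower genes (1395 and 1579 for independent lists), RBM17 and U2SURP 4112 and 4224 (1554 and 1882), and RBM17 and CHERP 3747 and 4050 (1679 and 2085). No simulated data set shared more than 1 called gene between any pair, which follows from simulating groups without change. A shift of the control group itself was not simulated, and it would appear alike in all 3 knockdowns. With 3 controls no split leaves 2 in each part, so some of the excess may come from the shared controls. U2SURP and CHERP knockdown, the most alike pair, also have adjoining library numbers, so their likeness cannot be told apart from a preparation batch.

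Direct contrasts set RBM17 knockdown apart from the other 2, whose library numbers adjoin. A preparation batch cannot be told apart from this pattern. SH2D3C was 9.57-fold higher in RBM17 than in CHERP knockdown (log2 3.26 ± 0.16, adjusted p = 2.21e-11) and 6.33-fold higher than in U2SURP knockdown (adjusted p = 4.38e-10). L1CAM (2.75 ± 0.11) and SYP (2.71 ± 0.075) were also higher than in CHERP knockdown, and DPYSL4 (2.00 ± 0.11) and EMILIN2 (1.99 ± 0.098) higher than in U2SURP knockdown. RPS6 was 12.6-fold lower than in U2SURP and 12.6-fold lower than in CHERP knockdown. TNXB (-2.37 ± 0.13) and EGR1 (-2.23 ± 0.28) were also lower than in U2SURP knockdown, and INPP5D (-2.25 ± 0.30) and LGR6 (-2.17 ± 0.13) lower than in CHERP knockdown. Neuronal genes differed by a median of 1.04 (fry adjusted p = 1.99e-08, and adjusted p = 0.00373 with an estimated correlation) against CHERP and 0.37 (fry adjusted p = 1.81e-07, and adjusted p = 0.00627 with an estimated correlation) against U2SURP knockdown. Ribosomal protein genes differed by -0.50 (fry adjusted p = 6.29e-04, and adjusted p = 0.587 with an estimated correlation) and -0.43 (fry adjusted p = 0.00107, and adjusted p = 0.549 with an estimated correlation), and heat shock genes by 0.52 (fry adjusted p = 6.29e-04, and adjusted p = 0.594 with an estimated correlation) and 0.70 (fry adjusted p = 4.16e-05, and adjusted p = 0.188 with an estimated correlation). Counts of different genes were 14964 against CHERP (7567 higher and 7397 lower in RBM17 knockdown) and 12899 against U2SURP knockdown (6667 and 6232).

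U2SURP and CHERP knockdown differed at fewer genes, 8078 (4340 higher and 3738 lower in U2SURP knockdown). GNG4, a G protein gamma subunit, was 3.63-fold higher in U2SURP knockdown (log2 1.86 ± 0.060, adjusted p = 2.07e-16), with CDC34, a ubiquitin-conjugating enzyme (1.63 ± 0.057), and CAVIN4 (1.58 ± 0.088) after it. CERK (-1.48 ± 0.057), IMPDH2, an enzyme of guanine nucleotide synthesis (-1.31 ± 0.067), and SKIDA1 (-1.22 ± 0.092) were lower in U2SURP knockdown. By list, neuronal genes differed by a median of 0.22 (fry adjusted p = 1.37e-05, and adjusted p = 0.0355 with an estimated correlation), endoplasmic reticulum chaperones by 0.23 (fry adjusted p = 0.00122, and adjusted p = 0.549 with an estimated correlation), p53 targets by -0.33 (fry adjusted p = 0.0147, and adjusted p = 0.734 with an estimated correlation) and heat shock genes by -0.22 (fry adjusted p = 0.00325, and adjusted p = 0.549 with an estimated correlation).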

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

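Genes named in the text by the rule set beforehand, and gene lists, are given here where 2 knockdowns moved them in opposite directions, each past the threshold, and the direct contrast (log2 difference, edgeR or fry) passed it too. The tests below of RPS6, neuronal genes and long non-coding RNAs were chosen after the results were seen, and the splits of the libraries before.

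RPS6 differed by -3.65 (adjusted p = 3.82e-21) between RBM17 and U2SURP knockdown and by -3.65 (adjusted p = 3.87e-21) between RBM17 and CHERP knockdown, since it fell in RBM17 knockdown and rose by 0.39 in both others. Reads counted at pseudogenes instead are argued against, because the 13 RPS6 pseudogenes summed changed by -0.383 CPM where RPS6 lost 1212. Reads left unassigned between RPS6 and its pseudogenes would be counted at neither. The files hold no rows for unassigned reads, so such a loss was not tested. A general fall of ribosomal protein mRNAs is argued against too: the other 77 genes had a median of -0.021 (SD 0.256), RPL3 being lowest at -0.77. An siRNA of the pool that acts on RPS6 directly could give the difference of -3.65 just as loss of RBM17 could; siRNA sequences were not used here and a single pool was tested, so these cannot be told apart.

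Neuronal genes differed by a median of 1.04 (fry adjusted p = 1.99e-08, and adjusted p = 0.00373 with an estimated correlation) between RBM17 and CHERP knockdown and 0.37 (fry adjusted p = 1.81e-07, and adjusted p = 0.00627 with an estimated correlation) between RBM17 and U2SURP knockdown. Against control the U2SURP side was small: 7 of 35 members rose and 13 fell (7 and 13 adjusted over the list alone), with a median of -0.06 (fry adjusted p = 0.00484), the call being lost with camera's preset (adjusted p = 0.421) and with an estimated correlation (adjusted p = 0.551; range over its alternatives 8.41e-04 to 0.551). With GC and length offsets the first median was 0.92 and the list still passed fry, against a trend of that kind as the whole cause. RNA from neurons would raise all abundant neuronal transcripts, and 6 of 9 with a low control level were called higher in RBM17 knockdown and 3 were not. Of these 3, CAMK2A was at 0.0115 CPM in control and 0.00906 in knockdown and THY1 at 0.0291 and 0.0231, where SNAP25 gained 2.21 CPM. SCG2 went from 0.178 to 0.269 CPM (log2 0.593, edgeR adjusted p = 0.0957), and a missed threshold excludes nothing. RNA from neurons is therefore left undecided for the rise in RBM17 knockdown. Such RNA in the RBM17 libraries would not lower the list below control in CHERP knockdown. There 19 of 35 members fell and 3 rose (median -0.50, fry adjusted p = 3.85e-06, and camera adjusted p = 0.158 with an estimated correlation). These values argue against it as the whole cause of the difference between RBM17 and CHERP knockdown. The mRNA of REST, a repressor of neuronal genes, changed by -0.078 ± 0.057 in RBM17 knockdown (adjusted p = 0.259) and 0.32 ± 0.057 in CHERP knockdown (adjusted p = 5.22e-05), which leaves REST activity open, since protein was not measured. An effect of the depleted proteins remains a hypothesis beside REST activity and RNA from neurons. For this and the other changes that set RBM17 knockdown apart, effects of its siRNA pool on other genes, such as RPS6, were not tested. A single pool was used, so they cannot be told apart from loss of RBM17.

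Long non-coding RNAs were lower in RBM17 knockdown, by a median of -0.495 against protein-coding genes. Other types fell too: pseudogenes had a median of -0.25 (1144 lower and 535 higher) and the remaining types -0.57 (419 lower and 41 higher). RBM17 knockdown libraries detected 36380 ± 685 genes and control libraries 37634 ± 677, with 96.3% and 94.5% of counts in protein-coding genes. With offsets for GC content and length the difference was still -0.42 (SE 0.0107), which argues against them as the whole cause. The offsets were fitted on genes of higher expression and extended to the rest, so this is less sure at low levels. Matching on mean CPM left -0.196 (SE 0.0102), so low expression could account for much of it but the remainder fell just short of the bound of 0.2 set for excluding it. Both SEs come from resampling genes within a single fit, not from edgeR. They carry no spread between libraries, and genes are not independent replicates. A batch of libraries cannot be told apart from the knockdown: long non-coding RNAs were also lower than in U2SURP knockdown (-0.26), and the RBM17 libraries form a block of library numbers.

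The remaining genes are given as log2 differences, with the highest adjusted p of each comparison. Between RBM17 and CHERP knockdown (25 genes with RPS6, adjusted p at most 5.37e-09) the differences were 4.39 for CHGA, 3.26 for SH2D3C, 2.75 for L1CAM, 2.71 for SYP, 2.67 for CLSTN2, 2.54 for TMEM145, 2.24 for RAB3C, 2.18 for SYT14 and 2.15 for CAVIN4. Smaller ones were 2.09 for EMILIN2, 2.03 for CHERP, 1.98 for CACNA1B, 1.97 for CDC34, 1.89 for GNG4, 1.81 for DPYSL4, 1.27 for SPRED2, 1.24 for HYOU1 and 0.78 for RPL17. Negative differences were -2.17 for LGR6, -1.99 for TNXB, -1.47 for ATP2A1, -1.36 for CDT1, -1.18 for RPL3 and -1.14 for SPATA18. Between RBM17 and U2SURP knockdown (17 genes with RPS6, adjusted p at most 2.94e-06) the differences were 2.66 for SH2D3C, 2.00 for DPYSL4, 1.99 for EMILIN2, 1.89 for CLSTN2, 1.62 for SYP, 1.59 for CERK, 1.36 for L1CAM, 0.92 for SKIDA1 and 0.76 for ATF4. Smaller ones were 0.53 for SPRED2 and 0.44 for HYOU1. Negative differences were -2.37 for TNXB, -1.37 for ATP2A1, -1.07 for RPL3, -0.96 for LGR6 and -0.94 for CDT1. Between U2SURP and CHERP knockdown (7 genes, adjusted p at most 7.07e-08) the differences were 1.86 for GNG4, 0.96 for CACNA1B and 0.87 for RAB3C. Negative differences were -1.97 for U2SURP, -1.31 for IMPDH2, -1.22 for SKIDA1 and -0.80 for ATF4. U2SURP here, and CHERP between RBM17 and CHERP knockdown, are siRNA targets, so their falls follow from the design.

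Among lists, RNAs sensitive to nonsense-mediated decay differed by -0.38 (fry adjusted p = 6.63e-04, and adjusted p = 0.549 with an estimated correlation) between RBM17 and U2SURP knockdown. Against control, 5 of 18 members rose and 11 fell (5 and 11 adjusted over the list alone), with a median of -0.22 (fry adjusted p = 0.0104) in RBM17 knockdown, and 11 of 18 members rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.22 (fry adjusted p = 0.0104) in U2SURP knockdown. The RBM17 call was lost under DESeq2 size factors (adjusted p = 0.0593), with camera's preset (adjusted p = 0.0848) and with an estimated correlation (adjusted p = 0.635; range over its alternatives 5.29e-04 to 0.635), and the U2SURP call with an estimated correlation (adjusted p = 0.542). Interferon response genes differed by -0.24 (fry adjusted p = 1.37e-05, and adjusted p = 0.473 with an estimated correlation) between RBM17 and CHERP knockdown. Against control, 4 of 24 members rose and 10 fell (5 and 10 adjusted over the list alone), with a median of -0.35 (fry adjusted p = 1.91e-04) in RBM17 knockdown, and 8 of 24 members rose and 7 fell (10 and 7 adjusted over the list alone), with a median of 0.10 (fry adjusted p = 4.25e-04) in CHERP knockdown. Both calls were lost with camera's preset (adjusted p = 0.315 and 0.233, ranges over the alternatives 1.71e-04 to 0.494 and 1.79e-04 to 0.494) and with an estimated correlation (adjusted p = 0.494 for both).

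For the 6 counts of changed genes, the 6 libraries of each comparison make 10 splits, too few for a share under 0.05. In fits of 2 groups, the real split called 15146 genes for RBM17, 12937 for U2SURP and 13623 for CHERP knockdown against control, 12834 between RBM17 and U2SURP, 14483 between RBM17 and CHERP and 8957 between U2SURP and CHERP knockdown. Only 1 of the 10 splits, the real one, called as many in each case, and the highest of the other splits called 0. Each other split mixes libraries of both groups, so the real difference widens its spread and few calls are to be foreseen. The 0 therefore decides nothing.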

How the results depend on the processing

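Offsets for GC content and length and the fit without RBM17 knockdown library 2 and control library 3 were chosen after seeing the data. The counts of changed genes stayed within 1.5 times under DESeq2 size factors, the DESeq2 Wald test, no filter, fits of 2 groups and both added settings. Which direction held more genes was less stable. Against control, where more genes were lower, more were higher under DESeq2 size factors, the Wald test and protein-coding genes alone in each knockdown and in the genes shared by all 3. With fits of 2 groups this held for RBM17 (7852 higher and 7294 lower), U2SURP (6494 higher and 6443 lower) and the shared genes (3126 higher and 2966 lower). With GC and length offsets it held for U2SURP (6681 higher and 6343 lower), CHERP (7605 higher and 6607 lower) and the shared genes (3394 higher and 3151 lower). Leaving both libraries out turned it for U2SURP and the shared genes. Between knockdowns, the offsets turned the balance to more lower genes for RBM17 and U2SURP (6347 higher and 6723 lower), RBM17 and CHERP (6796 higher and 8219 lower) and U2SURP and CHERP (4237 higher and 4965 lower). DESeq2 size factors moved log2 changes upward almost evenly, by a median of 0.0546 in RBM17 knockdown (0.0528 to 0.056), 0.0283 in U2SURP knockdown (0.0271 to 0.0298) and 0.0237 in CHERP knockdown (0.0226 to 0.0253), with the 5% and 95% quantiles over genes in brackets, which accounts for the turns under that setting. The DESeq2 Wald test uses size factors of this kind too. The shares of higher genes were the same under both settings, at 51.7% in RBM17, 52.9% in U2SURP and 51.4% in CHERP knockdown. For the remaining settings the cause was not tested. Requiring a change of at least 2-fold left 3404 (645 higher and 2759 lower) genes for RBM17, 1578 (637 higher and 941 lower) for U2SURP and 2347 (992 higher and 1355 lower) for CHERP knockdown. It left 2181 (543 higher and 1638 lower) between RBM17 and U2SURP, 3488 (981 higher and 2507 lower) between RBM17 and CHERP and 916 (387 higher and 529 lower) between U2SURP and CHERP knockdown, and 347 (91 higher and 256 lower) shared by all 3. These falls follow from the stricter rule. With protein-coding genes alone, 5354 genes were lower in RBM17 knockdown than in control, more than the 4433 protein-coding genes lower with all genes, and 4894 were lower than in CHERP knockdown. Scaling on fewer genes differs too, and the cause was not tested. In the fit of all genes, protein-coding genes were already more often higher in RBM17 (6308 higher and 4433 lower) and U2SURP knockdown (4789 and 4368). Among knockdowns against control, their own balance turned only for CHERP, from 4832 higher and 5048 lower to 5242 and 5079. With a mean of at least 5 CPM the correlations were 0.625 (RBM17 with U2SURP), 0.504 (RBM17 with CHERP) and 0.784 (U2SURP with CHERP). Without a filter RBM17 with CHERP gave 0.474 and U2SURP with CHERP 0.545, and Spearman's rho for RBM17 with U2SURP was 0.542; the cause was not tested. Leaving out each library in turn gave correlations of 0.468 to 0.566, 0.356 to 0.453 and 0.619 to 0.699 for these pairs, and counts of 14295 to 15585 for RBM17, 10603 to 12327 for U2SURP and 11958 to 13368 for CHERP knockdown. One named value reversed: CHERP in U2SURP knockdown, not called, was 0.108 with GC and length offsets (adjusted p = 0.0435, range over its alternatives 0.0435 to 0.989; the cause was not tested). Over all omissions of 1 library, 39 calls of named genes were lost and 1 gained, and 20 list calls lost and 8 gained. Of 87 list tests, 22 calls were lost with camera's preset and 69 with an estimated correlation. In RBM17 knockdown the list of endoplasmic reticulum chaperones (adjusted p = 0.0352) lost its call under DESeq2 size factors (adjusted p = 0.258, range over its alternatives 4.13e-04 to 0.735), with fits of 2 groups (0.324), with camera's preset (0.186) and without RBM17 knockdown library 2 (0.0644) or 3 (0.118) or control library 1 (0.0527) or 3 (0.07). No paired analysis was possible because replicate numbers follow accession order. The share of reads outside annotated exons and its alternatives were not run. Depth limits mainly genes of low counts.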

Other observations

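Gene families sharing the leading letters of their symbols, 111 stems with at least 15 tested protein-coding members, were scanned after the results were seen, as 333 tests adjusted together. With camera's preset 93 passed, and with an estimated correlation 0 passed. The 2 stems of smallest p with the preset in each knockdown are given, leaving out the ribosomal protein stems RPL and RPS. In RBM17 knockdown these were mitochondrial ribosomal proteins of the large subunit (MRPL), of which 40 of 49 rose and 2 fell (median 0.52; camera adjusted p = 3.57e-16 with its preset and adjusted p = 0.577 with an estimated correlation), and the ubiquitin-conjugating stem UBE, of which 32 of 41 rose and 2 fell (median 0.44; camera adjusted p = 8.92e-10 with its preset and adjusted p = 0.466 with an estimated correlation). Solute carriers (SLC) came first in U2SURP knockdown, where 42 of 329 rose and 167 fell (median -0.30; camera adjusted p = 5.25e-09 with its preset and adjusted p = 0.466 with an estimated correlation), followed by the transporter stem MFSD, of which 1 of 17 rose and 14 fell (median -0.41; camera adjusted p = 9.67e-07 with its preset and adjusted p = 0.466 with an estimated correlation). Collagens (COL) came first in CHERP knockdown, where 3 of 43 rose and 30 fell (median -0.54; camera adjusted p = 1.21e-16 with its preset and adjusted p = 0.363 with an estimated correlation), followed by SLC, of which 49 of 329 rose and 166 fell (median -0.29; camera adjusted p = 1.47e-07 with its preset and adjusted p = 0.466 with an estimated correlation).

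A hypothesis set before its test was that ion channel and synaptic vesicle genes outside the neuronal list and outside the named genes move like that list. In CHERP knockdown they may do so: 89 of 187 fell and 29 rose, with a median of -0.31 (fry adjusted p = 3.95e-07, and unadjusted p = 0.00883 by camera with an estimated correlation). In U2SURP knockdown, where no prediction was made, 29 rose and 64 fell, with a median of -0.19 (fry adjusted p = 1.06e-04, and unadjusted p = 0.115 by camera with an estimated correlation). In RBM17 knockdown 50 rose and 56 fell, with a median of 0.003 (fry adjusted p = 0.112, and unadjusted p = 0.705 by camera with an estimated correlation). The fall in CHERP knockdown was not particular to these genes. There SLC (49 of 329 higher, 166 lower, median -0.29) and TSPAN (0 of 22 higher, 16 lower, median -0.40) fell too, while stems such as GTF rose (15 of 24 higher, 1 lower). The prediction first counted a missed threshold as evidence against the hypothesis; that was dropped after the result, because a missed threshold excludes nothing, and the RBM17 part stays undecided.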
